A study of Rattus norvegicus with 28 samples.

How the data were processed

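RNA of primary hepatocytes from 2 adult female Sprague-Dawley rats (A and B) was measured on 28 Agilent 2-colour arrays. Per the labels, the cells were kept in culture for 48 h with 0.1 uM dexamethasone and treated for 24 h with compounds in 0.1% DMSO, with DMSO alone or with neither, and the RNA of 3 dishes was pooled. The 7 test groups were untreated cells, TCDD 0.01 and 1 nM, TCDF 0.1 and 10 nM, and PeCDF 0.02 and 2 nM, with 4 arrays each: 2 animals in 2 dye orientations, every array against DMSO RNA of the same animal. Within a compound the upper dose was 100 times the lower; the TCDF doses were 10 times and the PeCDF doses 2 times those of TCDD. It is not stated whether 1 preparation of DMSO RNA served all arrays of an animal.

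The scanner files of the authors hold mean spot signals and median local backgrounds in units of intensity, green for Alexa555 and red for Alexa647, per the file headers. The deposited log ratio is a log10 of red over green after the authors' background subtraction and dye normalization. In the deposited series table the log10 ratio is turned to test RNA over DMSO RNA, and it differed from the turned scanner value by at most 4.995e-06. Per the file headers the scans were read with Agilent Feature Extraction A.7.5.1, whereas the submitters' notes give 9.1. The headers date these Feature Extraction runs to 4 days, which were grouped here into 2 sessions: untreated and TCDD in the first, TCDF and PeCDF in the second. Extraction means this reading of the scans throughout, not the extraction of RNA. TCDD and the furans are therefore separated by session, and within a session the dye orientation coincides with the day.

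The intensities were read anew with R 4.3.3, limma 3.58.1 and the data.table package (version 1.17.8). Background was corrected by normexp with an offset of 50, each array was normalized by loess with the 2256 control spots at weight 0, and spots marked as non-uniform or as population outliers were dropped (1067 spots, 0.0921%). Spots of a probe were averaged, ratios were turned to test RNA over DMSO RNA, and the 2 orientations of an animal were averaged, so that a dye-swap pair counted as 1 replicate and 14 animal-level log2 ratios entered the fit. A value was missing where either orientation was (853 values, 0.175%). A probe was kept when it was well above background on all 4 arrays of a group in the test channel, or on at least 14 of 28 in the DMSO channel (37823 of 41012 probes). Of several probes for a gene name the brightest was used. Of the 37806 gene names 34848 were tested, 15218 of them with a gene symbol.

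Symbols came from the supplied table of RefSeq names, by accession (8031 probes), gene identifier (8669), symbol (1381) or synonym (426), and 22505 of 41012 probes had none. Genes without a symbol are in every count and are not named. No positions on the chromosomes were used.

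Groups were fitted together with limma (means of 7 groups, empirical Bayes, 3.20 prior and 7 residual degrees of freedom), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Tests were made of each group against DMSO, of the differences between compounds at the upper doses and between doses of a compound, and, with a moderated F-test, of the 3 lower doses. Lists were tested with camera (preset correlation 0.01), adjusted over 299 tests of 23 lists. Alternatives were an estimated correlation and fry. Camera accepts no missing values, so values of marked spots filled the gaps there. The lists covered the AHR battery and complex, NRF2 targets, CAR and PXR targets, constitutive cytochromes, glutathione transferases, conjugating enzymes, fatty acid oxidation, fatty acid and cholesterol synthesis, bile acids and transport, glucose metabolism, hepatocyte identity, acute phase, cell cycle, p53, unfolded protein response, clock and retinoid genes, and markers of Kupffer, stellate, endothelial and bile duct cells.

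Genes were named by a rule: the 10 largest increases and decreases with each upper dose, and the 5 largest each way in every other comparison, among called genes with a symbol and the same sign on all 4 arrays. For a difference between groups the 4 arrays of one had to lie wholly above or below those of the other. Named too were all measured AHR battery genes and up to 4 members of each other list with the smallest p at an upper dose. Not every gene that the rule picks is given in the text. Where every test channel of a higher gene was saturated, only a lower bound of the fold is given. Groups, tests, lists, the naming rule and all alternatives except 3 were fixed before the data were examined. Those 3 were the brightest unsaturated probe, the animal within a session as a block, and fits of 1 session alone.

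The alternatives, one at a time, were Agilent's own log ratio, the deposited series values, no background correction, no filter and a stricter filter on dim probes, every probe on its own, marked spots kept, the animal as a replicate block, array-level fits with a dye term or with the extraction day as a block, an intensity trend with robust variances, a minimum change of 1.5-fold, untreated RNA as the control, and each animal of a group left out. Overlap of calls was compared with independent calls and with 40 simulated draws of unchanged groups that share the DMSO RNA of an animal, which carried as much of the spread as the test RNA. With the animal as a replicate block TCDD 1 nM gave 3987 calls in place of 3677.

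The median signal over background was 30.3 to 63.3 over arrays in the test channel and 32.1 to 71.4 in the DMSO channel. The share of probes well above background in the test channel was 72.0% to 99.99%, and 20 to 162 probes per array were saturated there. The 2 orientations of an animal correlated by 0.00575 to 0.821, with a median of 0.449. The procedure was tested on simulated data in which 200 of 34848 genes changed. With TCDD 1 nM against DMSO it recovered 54% of changes of 0.25 log2, 80% of 0.5 and 98% of 1, with 6 false calls, and for TCDD 1 nM against PeCDF 2 nM 12%, 58% and 94%, with 1 false call. The simulated data held no effect of session or day and no deviation of an animal shared between groups. The numbers of false calls therefore do not cover errors from these sources. The number of arrays limits the precision. The labels were checked with Cyp1a1, which was higher in the labelled test RNA on every treated array with a value. No per-sample column that holds a measurement was left unused, and the label of each array placed it in a group. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.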

Results

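Hepatocytes of 2 rats were exposed for 24 h to TCDD (0.01 or 1 nM), a dioxin, to TCDF (0.1 or 10 nM), a furan, or to PeCDF (0.02 or 2 nM), a furan with 1 more chlorine. Each RNA was compared with the solvent (DMSO) RNA of the same animal, so a value below rests on n = 2 animals unless 1 is stated. The fits with limma called 3677 genes with TCDD 1 nM, 1529 with PeCDF 2 nM and 822 with TCDF 10 nM. At the lower doses they called 157, 0 and 1 genes, in the same order of compounds. Errors are standard errors of the log2 ratio from the fit.

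**Figure D1:**
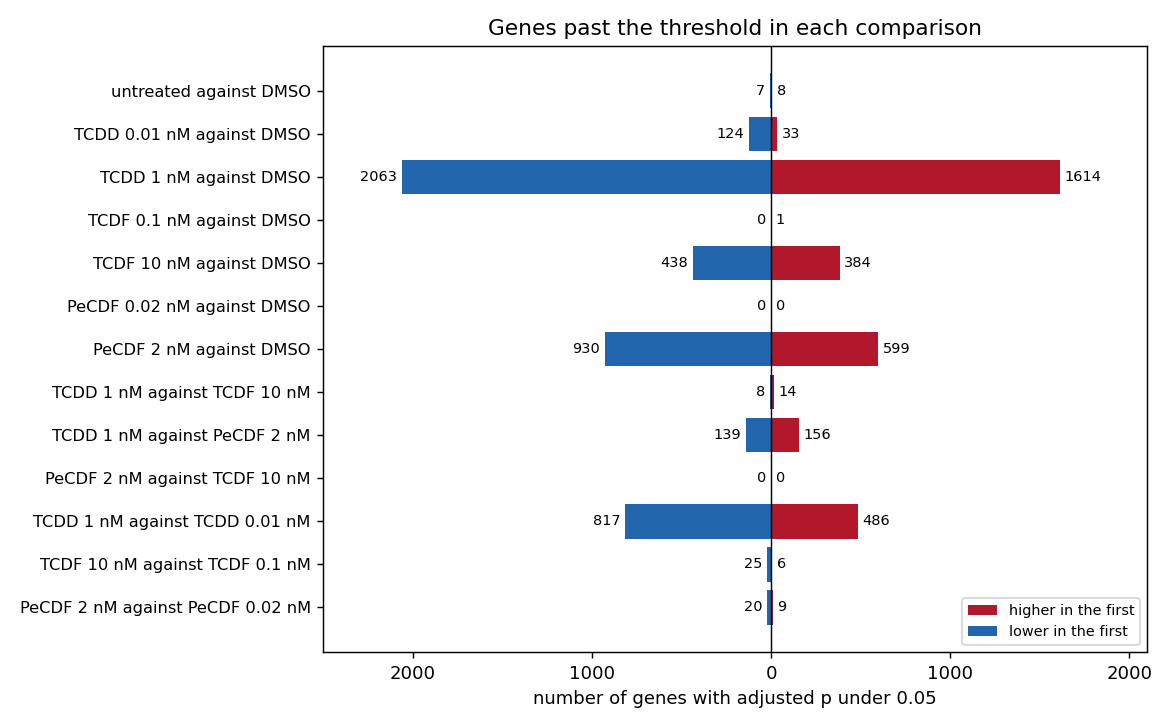
Number of genes called by limma in each comparison, split into higher and lower. The count was largest with TCDD 1 nM and close to 0 with the lower furan doses.

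Few genes were called between untreated cells and cells with DMSO. Ebag9, a tumour-associated antigen of the Golgi, was 1.57-fold higher in untreated cells (log2 ratio 0.65 ± 0.08, adjusted p = 0.0393), though another probe of this gene had 0.04. Nptn, a cell adhesion protein, was 1.41-fold higher (0.50 ± 0.06), and Stxbp6, a regulator of vesicle fusion, 1.31-fold (0.38 ± 0.05). Among the 12 measured genes of the aryl hydrocarbon receptor (AHR) battery none passed, and Cyp1a1, the best known target of this receptor, had a log2 ratio of 0.06 ± 0.11. In total 15 genes passed, 8 higher and 7 lower, and 26 did with the animal as a block. The counts were 24 higher and 450 lower without animal A, 142 and 625 without animal B, and 0 with the groups of the first extraction session alone.

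Cyp1b1, Ereg and Areg were among the largest increases with TCDD 1 nM. Cyp1b1, which oxidises oestrogens and aromatic hydrocarbons, rose 15.2-fold (log2 ratio 3.93 ± 0.15, adjusted p = 8.97e-07), though another probe of this gene gave 3.08-fold. Ereg and Areg, ligands of the epidermal growth factor receptor, rose 6.91-fold (2.79 ± 0.18) and 5.53-fold (2.47 ± 0.23). Aldh3a1, an aldehyde dehydrogenase, rose 4.87-fold (2.28 ± 0.36), and Tiparp, a mono-ADP-ribosyltransferase that restrains the receptor, 3.57-fold (1.84 ± 0.25). Cxcl2 and Cxcl1, neutrophil attractants, rose 3.76-fold (1.91 ± 0.39) and 3.39-fold (1.76 ± 0.22), the kinase Map3k8 3.68-fold (1.88 ± 0.20) and the transcription factor Pou3f1 3.23-fold (1.69 ± 0.08). Cyp1a2, a caffeine-oxidising cytochrome, rose 3.52-fold (1.82 ± 0.12) with 3 of 4 test channels saturated, and 4.89-fold on an unsaturated probe. Cyp1a1 was saturated on all 4 arrays and rose at least 3.08-fold. Animal A lacked a value in 1 orientation, so the call rests on animal B alone (n = 1). The bound also takes in the other orientation of animal A.

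Cyp7a1, Fasn and Acly were among the largest decreases with TCDD 1 nM. Cyp7a1, the first enzyme of bile acid synthesis, had a log2 ratio of -2.05 ± 0.35 (adjusted p = 0.00433). Fasn and Acly, which build fatty acids and their acetyl-CoA precursor, had -1.90 ± 0.29 and -1.87 ± 0.15. Slc2a5, a fructose transporter, had -1.82 ± 0.09, and Pfkfb1, the liver enzyme that makes and degrades fructose 2,6-bisphosphate, -1.63 ± 0.04 (adjusted p = 1.17e-07). Ugt1a1, which conjugates bilirubin, had -1.56 ± 0.20, and Bbox1, the last enzyme of carnitine synthesis, -1.63 ± 0.19. Tmem255b, a little studied membrane protein, had -1.81 ± 0.13, Zfp354a, a zinc finger protein of kidney and liver, -1.69 ± 0.09, and Emp1, an epithelial membrane protein, -1.60 ± 0.09 (another probe -0.59). Of the 3677 genes called, 1614 rose and 2063 fell, and over 2-fold changes were seen in 34 and 71. The count was 1595 without animal B and 2901 with the groups of the first session alone, and the balance turned to 1549 higher and 1428 lower with no background correction.

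Of the 12 measured AHR battery genes 11 rose with TCDD 1 nM (11 adjusted over the list alone), with a median log2 ratio of 1.40. The list test with camera gave adjusted p = 1.4e-14, and adjusted p = 0.0123 with an estimated correlation. Beside the cytochromes, Nqo1, a quinone reductase, rose 2.91-fold (1.54 ± 0.18), Nfe2l2, the oxidant-response regulator NRF2, 2.39-fold (1.25 ± 0.09), and Ugt1a6, which conjugates phenols, 1.74-fold (0.80 ± 0.18). Gsta2, a glutathione transferase, rose 1.87-fold (0.90 ± 0.23), Ugdh, which makes the glucuronic acid donor, 1.38-fold (0.46 ± 0.09), and Slc7a5, an amino acid transporter, 1.17-fold (0.22 ± 0.06). Cyp2s1, an extrahepatic cytochrome, had 0.04 ± 0.04. None of the 7 genes of the receptor complex passed (0 adjusted over the list alone, 0.353 for the list), Arnt among them with -0.11 ± 0.04.

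**Figure D2:**
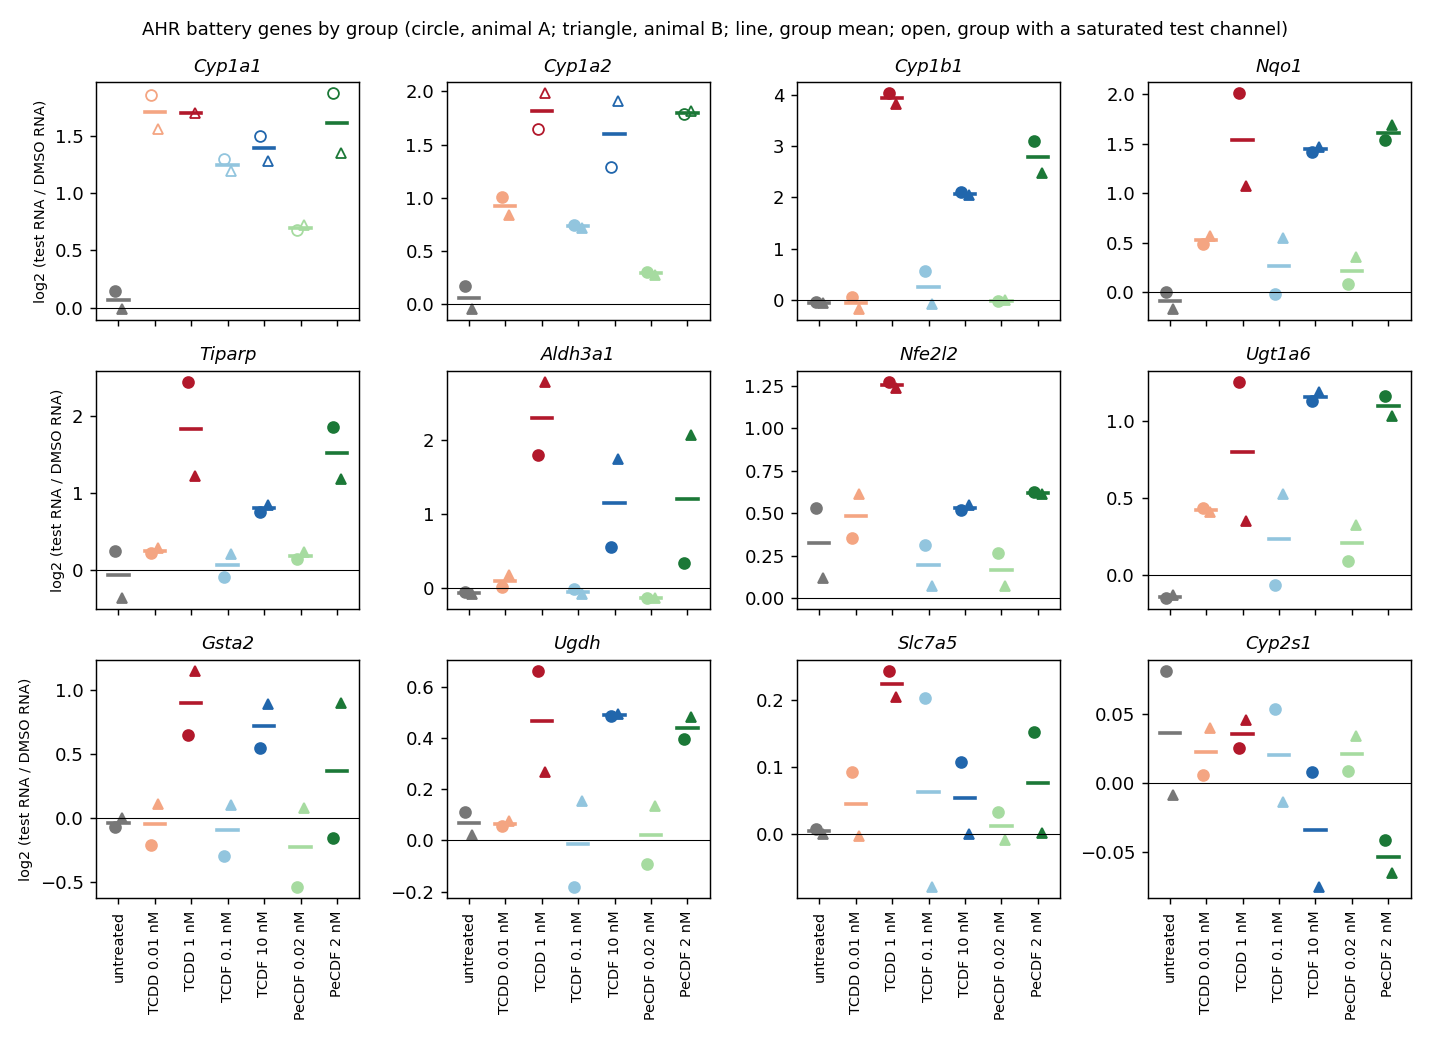
Log2 ratio to DMSO of the measured AHR battery genes in each group, with 1 point per animal. Open points mark groups with a saturated test channel, in which the ratio is too low, and Cyp1a1 has no point for TCDD 1 nM animal A.

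Glucose metabolism, fatty acid oxidation and bile acid handling fell as lists with TCDD 1 nM. Of 21 genes of glucose metabolism 13 fell (14 adjusted over the list alone) and 0 rose, with a median of -0.79 (adjusted p = 1.52e-13, and adjusted p = 0.0216 with an estimated correlation). Among them were Slc37a4, the glucose 6-phosphate transporter (-1.38 ± 0.07), and Gckr, the glucokinase regulator (-1.20 ± 0.06). Of 26 genes of fatty acid oxidation and PPARA targets 16 fell (19 adjusted over the list alone), with a median of -0.35 (4.48e-13, and adjusted p = 0.047 with an estimated correlation). These included Angptl4, an inhibitor of lipoprotein lipase (-1.46 ± 0.09), Fgf21, a fasting hormone (-0.89 ± 0.06), and Cpt2, a carnitine acyltransferase (-0.37 ± 0.04). Of 23 genes of bile acid synthesis and hepatic transport 16 fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -0.53 (2.08e-12, and adjusted p = 0.047 with an estimated correlation). Nr1h4, the bile acid receptor FXR, had -1.07 ± 0.12, Abcb4, which exports phospholipid, -0.84 ± 0.04, Abcb11, the bile salt pump, -0.80 ± 0.09, and Slco1a1, an anion transporter, -0.80 ± 0.09.

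Fatty acid synthesis genes fell in 8 of 21 cases with TCDD 1 nM (11 adjusted over the list alone), among them Acaca, the acetyl-CoA carboxylase (-0.90 ± 0.06, though another probe had -0.03), Scd, a desaturase (-0.91 ± 0.08), and Srebf1, a lipogenic transcription factor (-0.67 ± 0.07). This list lost its call, with adjusted p = 0.228 with an estimated correlation. Conjugating enzymes fell in 12 of 20 cases and rose in 2 (14 and 2 adjusted over the list alone), such as the sulfotransferases Sult1b1 (-1.05 ± 0.13 with 2 of 4 DMSO channels saturated, -1.23 ± 0.13 on an unsaturated probe), Sult2a6 (-0.97 ± 0.09) and Sult2a2 (-0.66 ± 0.07), and Ugt2a1, a glucuronosyltransferase (-0.69 ± 0.06); adjusted p = 0.293 with an estimated correlation. Targets of CAR and PXR fell in 7 of 17 cases and rose in 1 (8 and 1 adjusted over the list alone), with the cytochromes Cyp2b3 at -0.86 ± 0.05, Cyp2c6v1 at -0.77 ± 0.08, Cyp3a18 at -0.70 ± 0.07 and Cyp2b2 at -0.42 ± 0.06; adjusted p = 0.171 with an estimated correlation. Constitutive and sex-dependent cytochromes fell in 7 of 23 cases and rose in 2 (12 and 3 adjusted over the list alone), with adjusted p = 0.537 with an estimated correlation. Cyp4f4, a fatty acid hydroxylase, had -1.11 ± 0.08, Cyp17a1, of steroid synthesis, -0.96 ± 0.08, and Cyp2c22, a retinoid hydroxylase, -0.81 ± 0.16, whereas Cyp2a1, a testosterone hydroxylase, rose 2.32-fold (1.21 ± 0.21).

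NRF2 targets rose in 7 of 20 cases with TCDD 1 nM and fell in 1 (8 and 2 adjusted over the list alone), with adjusted p = 0.388 with an estimated correlation. Txnrd1, a thioredoxin reductase, rose 1.71-fold (0.77 ± 0.06), Gclm, of glutathione synthesis, 1.47-fold (0.55 ± 0.06), and Slc7a11, the cystine importer, 1.36-fold (0.45 ± 0.04). Glutathione transferases fell in 4 of 17 cases and rose in 1 (7 and 1 adjusted over the list alone), among them Mgst3 (-0.65 ± 0.12) and Mgst1 (-0.53 ± 0.10), which detoxify lipid peroxides; adjusted p = 0.546 with an estimated correlation. Of 26 hepatocyte identity genes 8 fell and 1 rose (11 and 1 adjusted over the list alone), with adjusted p = 0.206 with an estimated correlation. Arg1, of the urea cycle, had -0.85 ± 0.10 with 2 of 4 DMSO channels saturated, and Tdo2, which degrades tryptophan, -0.48 ± 0.06. Retinoid metabolism fell in 7 of 25 cases and rose in 1 (12 and 1 adjusted over the list alone), with Rdh7, a retinol dehydrogenase, at -0.99 ± 0.16 and Dhrs3, a retinal reductase, at -0.61 ± 0.06; adjusted p = 0.118 with an estimated correlation. Clock genes fell in 3 of 16 cases and rose in 1 (4 and 1 adjusted over the list alone), with the repressor Bhlhe40 at -0.60 ± 0.10; adjusted p = 0.21 with an estimated correlation.

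Some markers of other liver cells were also lower with TCDD 1 nM, though none of their lists held a call. Over all 34848 genes tested 2063 were called lower. Of 18 Kupffer cell and leukocyte markers 5 fell (7 adjusted over the list alone), with adjusted p = 0.293 with an estimated correlation. Lyz2, a lysozyme, had -0.60 ± 0.08, C1qc, of complement, -0.50 ± 0.12, Vsig4, a complement receptor, -0.48 ± 0.09, and Cybb, of the phagocyte oxidase, -0.34 ± 0.09. Of 18 stellate cell and fibroblast markers 4 fell (4 adjusted over the list alone, 0.264 for the list), with Lox, a collagen crosslinker, at -0.91 ± 0.20 and Vim, an intermediate filament, at -0.75 ± 0.10. Of 15 cholangiocyte markers 2 fell (2 adjusted over the list alone, 0.0679 for the list), Anxa13, an epithelial annexin, with -1.35 ± 0.08 and Prom1, a membrane glycoprotein, with -0.49 ± 0.12. None of 15 endothelial markers passed (0 adjusted over the list alone, 0.755 for the list). These values stand beside the hepatocyte lists above.

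Lists without a call with TCDD 1 nM still held single genes that moved. Acute phase genes rose in 5 of 21 cases and fell in 5 (5 and 6 adjusted over the list alone, 0.365 for the list), with Lbp, which binds endotoxin, up 1.38-fold (0.47 ± 0.05) and Il6r, the interleukin 6 receptor, at -0.69 ± 0.09. Genes of the p53 response rose in 4 of 19 cases and fell in 2 (6 and 3 adjusted over the list alone, 0.211 for the list), with Sesn1, a stress-response inhibitor of mTORC1, at -1.09 ± 0.12 and Bax, which promotes apoptosis, up 1.22-fold (0.28 ± 0.06). Targets of the unfolded protein response and ATF4 rose in 4 of 17 cases and fell in 5 (4 and 5 adjusted over the list alone, 0.211 for the list), with Herpud1, of protein degradation, at -0.63 ± 0.09 and Atf4 up 1.18-fold (0.24 ± 0.04). Cholesterol synthesis rose in 2 of 25 cases and fell in 3 (3 and 3 adjusted over the list alone, 0.941 for the list), with Dhcr7, its last reductase, at -0.84 ± 0.16. Cell cycle genes fell in 2 of 26 cases (3 adjusted over the list alone, 0.259 for the list), Ccnd1, a cyclin, with -0.27 ± 0.07 and Ccne2, another, with -0.18 ± 0.05.

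Cyp1b1, Cyp1a2 and Nqo1 were among the largest increases with TCDF 10 nM. Cyp1b1 rose 4.21-fold (2.07 ± 0.15, adjusted p = 0.0002; another probe 1.26-fold), Nqo1 2.72-fold (1.44 ± 0.18) and Ugt1a6 2.23-fold (1.16 ± 0.18). Cyp1a2 rose 3.04-fold (1.60 ± 0.12) with 3 of 4 test channels saturated, and 5.58-fold on another probe, and Cyp1a1 at least 2.62-fold. Cyp2a1 rose 2.30-fold (1.20 ± 0.21), Cxcl1 2.28-fold (1.19 ± 0.22), Ceacam4, an adhesion molecule, 2.07-fold (1.05 ± 0.14), Selenbp1, which oxidises methanethiol, 1.79-fold (0.84 ± 0.09) and Defb1, an antimicrobial peptide, 1.79-fold (0.84 ± 0.07). Lower genes were Tmem255b (-1.57 ± 0.13), Slc2a5 (-1.41 ± 0.09), Ccn2, a matrix-associated growth factor (-1.34 ± 0.14), Acly (-1.27 ± 0.15, 1 of 4 DMSO channels saturated) and Onecut1, a liver transcription factor (-1.14 ± 0.16). Emp1 (-1.07 ± 0.09, another probe -0.14), Fam117b, of unknown function (-1.05 ± 0.12), Pfkfb1 (-0.94 ± 0.04) and Anxa13 (-0.94 ± 0.08) were lower too.

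With TCDF 10 nM the AHR battery and glucose metabolism were the lists whose calls held with both settings of the correlation. Of 12 battery genes 7 rose (10 adjusted over the list alone), with a median of 0.98 (1.4e-14, and adjusted p = 0.0123 with an estimated correlation). Nfe2l2 rose 1.45-fold (0.53 ± 0.09) and Ugdh 1.40-fold (0.49 ± 0.09), while Aldh3a1 (1.15 ± 0.36, adjusted p = 0.174), Tiparp (0.80 ± 0.25, adjusted p = 0.159) and Gsta2 (0.72 ± 0.23) did not pass. Of 21 glucose genes 9 fell (14 adjusted over the list alone), with a median of -0.34 (2.17e-16, and adjusted p = 0.0168 with an estimated correlation), among them Slc37a4 (-0.90 ± 0.07) and Gckr (-0.81 ± 0.06). Fatty acid oxidation fell in 4 of 26 cases (10 adjusted over the list alone), with Angptl4 at -0.72 ± 0.09; adjusted p = 0.0991 with an estimated correlation. Bile acid genes fell in 2 of 23 cases (14 adjusted over the list alone), Abcb4 with -0.58 ± 0.04; adjusted p = 0.0792 with an estimated correlation. Fatty acid synthesis fell in 4 of 21 cases (8 adjusted over the list alone), with Scd at -0.69 ± 0.08 (2 of 4 DMSO channels saturated) and Acaca at -0.72 ± 0.06 (another probe 0.03); adjusted p = 0.236 with an estimated correlation. No Kupffer cell marker passed (0 adjusted over the list alone; adjusted p = 0.452 with an estimated correlation), and of the stellate cell markers Vim did (-0.47 ± 0.10). In total 384 genes rose and 438 fell. The count was 64 without animal A, 260 without animal B, 469 with the groups of the second session alone and 1353 with the animal within a session as a block. The balance turned in array-level fits with a dye term (1567 higher and 1255 lower) and with the day as a block (1493 and 1199), and Agilent's log ratio gave 111 and 310.

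PeCDF 2 nM raised Cyp1b1 and the growth factor ligands Ereg and Areg. Cyp1b1 rose 6.86-fold (2.78 ± 0.15, adjusted p = 6.73e-05; another probe 1.48-fold), Ereg 2.10-fold (1.07 ± 0.18) and Areg 1.99-fold (0.99 ± 0.23). Cyp1a2 rose 3.48-fold (1.80 ± 0.12) with 3 of 4 test channels saturated, and 4.58-fold on another probe, and Cyp1a1 at least 3.06-fold. Nqo1 rose 3.06-fold (1.61 ± 0.18), Tiparp 2.88-fold (1.53 ± 0.25), Ugt1a6 2.14-fold (1.10 ± 0.18), Cyp2a1 1.94-fold (0.95 ± 0.21) and Pkdcc, a secreted kinase, 1.90-fold (0.93 ± 0.11). Lower genes were Cyp7a1 (-1.46 ± 0.35, adjusted p = 0.0471), Fasn (-1.43 ± 0.29), Slc2a5 (-1.42 ± 0.09), Onecut1 (-1.30 ± 0.16), Acly (-1.26 ± 0.15) and Tmem255b (-1.19 ± 0.13). Srpra, of protein secretion (-1.12 ± 0.26, though another probe had 0.17), Serpina5, a protease inhibitor (-0.91 ± 0.14), Ccn2 (-0.89 ± 0.14) and Emp1 (-0.85 ± 0.09, another probe -0.02) were lower too.

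The lists whose calls held with PeCDF 2 nM were again the AHR battery and glucose metabolism. Of 12 battery genes 8 rose (9 adjusted over the list alone), with a median of 1.15 (2.82e-13, and adjusted p = 0.0129 with an estimated correlation), Nfe2l2 1.54-fold (0.62 ± 0.09) and Ugdh 1.36-fold (0.44 ± 0.09) among them. Aldh3a1 (1.20 ± 0.36, adjusted p = 0.103) and Gsta2 (0.37 ± 0.23) did not pass. Of 21 glucose genes 10 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -0.35 (1.66e-12, and adjusted p = 0.0237 with an estimated correlation), including Slc37a4 (-0.78 ± 0.07), Pfkfb1 (-0.74 ± 0.04) and Gckr (-0.64 ± 0.06). Fatty acid oxidation fell in 6 of 26 cases (10 adjusted over the list alone), with Angptl4 at -0.50 ± 0.09; adjusted p = 0.228 with an estimated correlation. Fatty acid synthesis fell in 5 of 21 cases (10 adjusted over the list alone), with Acaca at -0.66 ± 0.06 (another probe -0.11); adjusted p = 0.335 with an estimated correlation. Bile acid genes fell in 4 of 23 cases (12 adjusted over the list alone), Abcb4 with -0.32 ± 0.04; adjusted p = 0.136 with an estimated correlation. No Kupffer cell marker passed (0 adjusted over the list alone, 0.571 for the list). Of 18 stellate cell markers 2 rose and 1 fell (2 and 2 adjusted over the list alone, 0.0745 for the list), with Dcn, a matrix proteoglycan of fibroblasts, up 1.15-fold (0.20 ± 0.05), and of 15 cholangiocyte markers Anxa13 fell (-0.77 ± 0.08; 2 adjusted over the list alone, 0.403 for the list). In total 599 genes rose and 930 fell. The count was 136 without animal A, 655 without animal B, 1054 with the groups of the second session alone and 2647 with the animal within a session as a block.

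**Figure D3:**
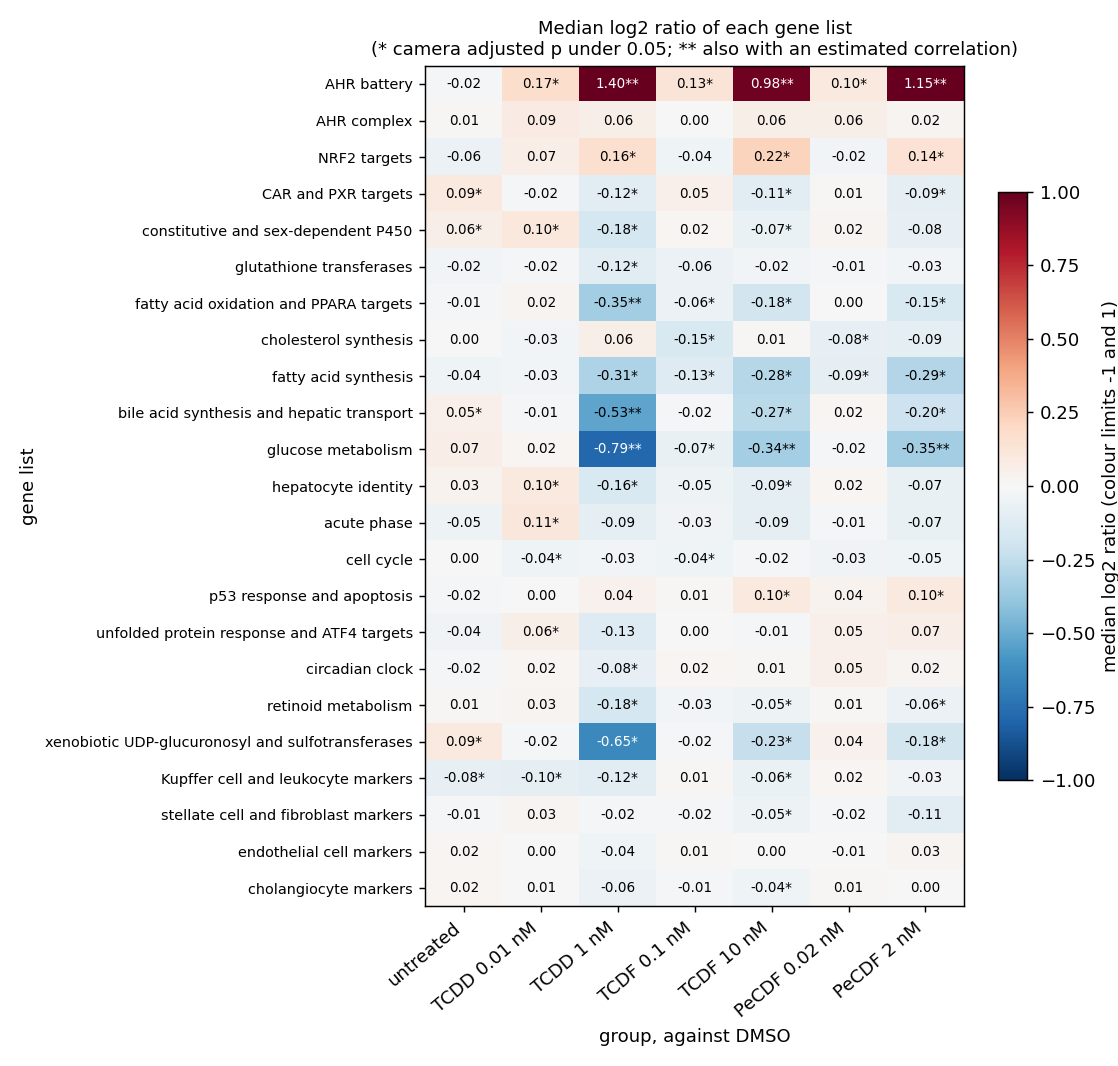
Median log2 ratio of each gene list in each group against DMSO, with 1 star where the camera test called the list and 2 where the call held with an estimated correlation. Colour is limited to 1 log2 unit either way, which the AHR battery exceeded.

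TCDD 1 nM and TCDF 10 nM, doses that differ 10 times, differed in Ereg, Cyp1b1 and Pou3f1. Ereg was 4.92-fold higher with TCDD (difference 2.30 ± 0.25, adjusted p = 0.0203), Cyp1b1 3.62-fold (1.85 ± 0.21) and Pou3f1 2.58-fold (1.37 ± 0.11), while Tpbg, a membrane glycoprotein, was 1.48-fold (0.56 ± 0.07) and Atp11a, a lipid flippase, 1.46-fold higher (0.55 ± 0.07). Pfkfb1 (-0.69 ± 0.06), Xab2, of repair and splicing (-0.54 ± 0.07), and Polg2, of the mitochondrial polymerase (-0.38 ± 0.05), were lower with TCDD. No difference was called for Nqo1 (0.10, 95% interval -0.48 to 0.67), Ugt1a6 (-0.36, -0.91 to 0.20) or Tiparp (1.03, 0.26 to 1.81, adjusted p = 0.282). Cyp1a1 was saturated with both compounds and gave no fold between them, and Cyp1a2 had a difference of -0.19 (-0.75 to 0.37) on an unsaturated probe. In total 14 genes were higher and 8 lower with TCDD, and 36 differed with the animal as a block. This balance turned in array-level fits with a dye term (588 higher and 1946 lower) and with the animal within a session as a block (88 and 172). The 2 compounds were extracted in different sessions, and the count was 7 without TCDD animal B, 1770 without TCDD animal A (218 higher and 1552 lower), 3 without TCDF animal A and 39 without TCDF animal B.

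Against PeCDF 2 nM, a dose 2 times that of TCDD, TCDD 1 nM differed in more genes in the main fit (295, and 22 against TCDF 10 nM). With Agilent's log ratio these counts were 7 and 2, and the order did not hold without TCDD animal B. Ereg was 3.29-fold higher with TCDD (1.72 ± 0.25, adjusted p = 0.0209), Cyp1b1 2.22-fold (1.15 ± 0.21), Pou3f1 2.11-fold (1.08 ± 0.11), Map1b, of microtubules, 1.81-fold (0.86 ± 0.16) and Sf3b2, of splicing, 1.80-fold (0.85 ± 0.14). Other probes had 0.05 to 0.24 for Map1b with TCDD and 0.04 for Sf3b2 with PeCDF, each against DMSO. Cdo1, which oxidises cysteine (-1.24 ± 0.23), Angptl4 (-0.97 ± 0.12), Zfp354a (-0.96 ± 0.13), F11, a clotting factor (-0.95 ± 0.13), and Dusp1, a phosphatase of MAP kinases (-0.94 ± 0.15), were lower with TCDD. Of the glucose genes 6 were lower with TCDD (10 adjusted over the list alone; adjusted p = 0.0792 with an estimated correlation) and of the fatty acid oxidation genes 4 (11 adjusted over the list alone; adjusted p = 0.0991 with an estimated correlation). No difference was called for Nqo1 (-0.07, 95% interval -0.65 to 0.50) or Tiparp (0.31, -0.47 to 1.08). Cyp1a1 was again saturated, and Cyp1a2 had 0.09 (-0.47 to 0.66) on the unsaturated probe. In total 156 genes were higher and 139 lower with TCDD, or 1616 and 2281 in array-level fits with a dye term. With the animal as a block 428 genes differed, and 1242 did with the animal within a session as a block. Session and compound again coincide, and the count was 2293 without TCDD animal A (564 higher and 1729 lower), 6 without TCDD animal B, 6 without PeCDF animal A and 90 without PeCDF animal B.

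Between the 2 furans, PeCDF 2 nM and TCDF 10 nM, limma called 0 genes, with 990 at unadjusted p under 0.05. The largest battery differences were those of Tiparp (0.72 ± 0.35, with 0 inside the 95% interval) and Cyp1b1 (0.70 ± 0.21, 95% interval 0.24 to 1.17), and that of Ereg was 0.58 (0.02 to 1.14). For Nqo1 it was 0.17 (-0.41 to 0.74), and for Cyp1a2 -0.28 (-0.85 to 0.28) on the unsaturated probe, while Cyp1a1 was saturated with both furans. Over the 4468 genes called at any upper dose, 3677 of them with TCDD, the interval of the difference between the furans lay within 1.5-fold for 95.7%. The share was 83.2% for TCDD 1 nM against TCDF 10 nM and 78.0% against PeCDF 2 nM. The median absolute log2 ratio of these genes to DMSO was only 0.132 with TCDF 10 nM and 0.154 with PeCDF 2 nM. Changes so far under 1.5-fold make a high share likely, so it does not show that the furans act alike. The count between the furans stayed at 0 with the animal as a block and with the second session alone, and became 11 without PeCDF animal B and 23 without TCDF animal B.

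The genes called with 1 compound overlapped those called with another. Of the 384 genes higher with TCDF 10 nM 249 were also higher with TCDD 1 nM, where independent calls would give 17.8, and of the 438 lower 401 were also lower, against 25.9. Of the 599 higher with PeCDF 2 nM 298 were also higher with TCDD, against 27.8, and of the 930 lower 494, against 55.1. The furans shared 261 higher and 335 lower genes. Opposite calls numbered 1 (TCDD and TCDF), 14 (TCDD and PeCDF) and 0 (the furans), and 181 genes rose and 311 fell with all 3 compounds. Simulated unchanged groups that share the solvent RNA of an animal gave 0 shared calls at these doses. No gene changed in them, so hardly any could be called. The 0 therefore does not show how far a shared solvent RNA adds to the overlap of real calls. Their log2 ratios had a correlation of 0.501. That correlation follows from the assumed equal spread of solvent and test RNA, so it is not a measured reference. The correlations seen were 0.534 and 0.440 for TCDD with TCDF and PeCDF, and 0.773 for the furans. Across animals, where no solvent RNA is shared, the correlations were 0.552 and 0.384 for TCDD with TCDF, 0.430 and 0.166 for TCDD with PeCDF, and 0.449 and 0.661 for the furans.

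**Figure D4:**
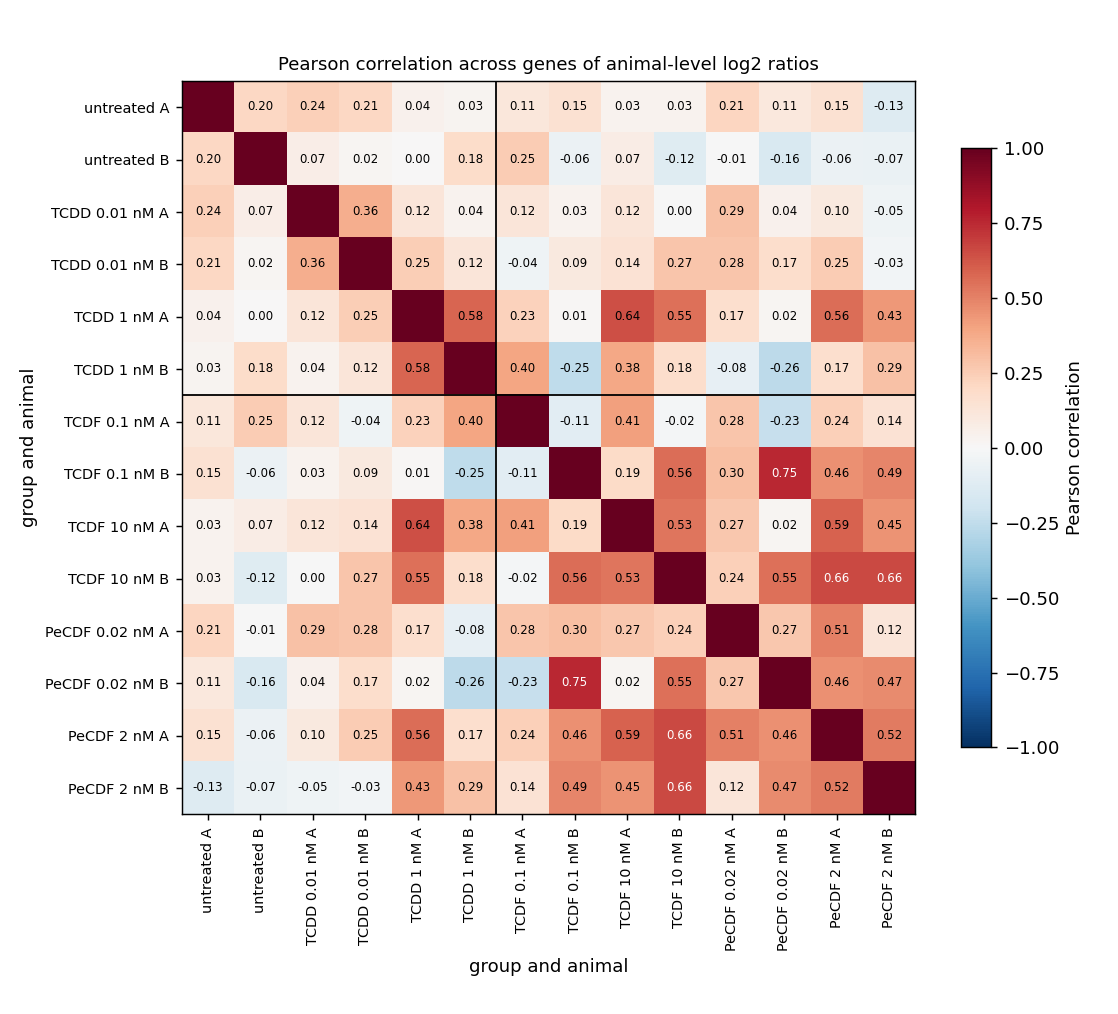
Correlation of the log2 ratios of all genes between the animal-level profiles, with black lines between the extraction sessions. Profiles of the same animal may share a solvent RNA, which is not stated.

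Cyp1a1 had the largest change among the genes called with TCDD 0.01 nM and with TCDF 0.1 nM. It rose at least 3.27-fold with TCDD 0.01 nM, where it was saturated, and 2.37-fold with TCDF 0.1 nM (1.24 ± 0.11, adjusted p = 0.0483, 3 of 4 test channels saturated), and had a ratio of 1.62 with PeCDF 0.02 nM (0.70 ± 0.11, adjusted p = 0.44, 1 of 4 saturated). With TCDD 0.01 nM Cyp1a2 rose 1.90-fold (0.92 ± 0.12; another probe 0.85, adjusted p = 0.0953), Entpd5, a nucleotidase of the endoplasmic reticulum, 1.45-fold (0.53 ± 0.07), Ero1a, of disulfide formation, 1.21-fold (0.28 ± 0.05), and Hsd17b2, which inactivates sex steroids, 1.19-fold (0.25 ± 0.04). Gpr141, an orphan receptor (-0.51 ± 0.03), Phka1, a phosphorylase kinase subunit (-0.49 ± 0.04), Kif5a, a motor of neurons (-0.43 ± 0.03), Bfsp1, of the lens (-0.42 ± 0.03), and Luc7l3, of splicing (-0.41 ± 0.06), were lower, though Gpr141 was well above background on 1 of 4 test channels and Bfsp1 on 2. Of the 12 battery genes 2 rose with TCDD 0.01 nM (4 adjusted over the list alone; adjusted p = 0.0581 with an estimated correlation), 1 with TCDF 0.1 nM (2 adjusted over the list alone; adjusted p = 0.0991 with an estimated correlation) and 0 with PeCDF 0.02 nM (1 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation). Of the 33 genes higher with TCDD 0.01 nM 26 were also higher with 1 nM, against 1.53 by independent calls, and of the 124 lower 3 were also lower, against 7.34. Opposite calls numbered 3, against 7.70, and simulated unchanged groups that share the solvent RNA gave at most 1 shared call in either direction. As no gene changed in those groups, this does not show how far a shared solvent RNA adds to the overlap. Array-level fits turned the balance of 33 higher and 124 lower, with 450 higher and 272 lower with a dye term and 414 and 258 with the extraction day as a block. With PeCDF 0.02 nM limma called 0 genes (2651 at unadjusted p under 0.05), and with TCDF 0.1 nM Cyp1a1 alone (2654 at unadjusted p under 0.05), or 2 with the animal as a block. With the groups of their own session alone the counts were 14, 0 and 0, and without animal A or B they were 245 and 601 (TCDD), 34 and 42 (TCDF), and 0 and 157 (PeCDF).

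The 3 lower doses, which differ 10 times between TCDD and TCDF and 2 times between TCDD and PeCDF, differed among each other in 31 genes. This count fell to 4 with the stricter filter on dim probes, which tests fewer genes, and to 1 with a change of at least 1.5-fold. TCDD 0.01 nM and TCDF 0.1 nM differed in 48 genes, 8 higher and 40 lower with TCDD, and TCDD and PeCDF 0.02 nM in 28, all lower with TCDD. Session and compound coincide in these comparisons of TCDD with a furan. The lower furan doses differed in 0 genes by limma, with 622 at unadjusted p under 0.05. The count of 31 became 60 without TCDD animal A, 233 without TCDD animal B, 48 without TCDF animal A and 150 without PeCDF animal B.

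Raising the dose 100 times changed Cyp1b1 with every compound in the main fit. The upper dose of TCDD was 15.9-fold over the lower for this gene (3.99 ± 0.21, adjusted p = 3.22e-05), that of PeCDF 6.91-fold (2.79 ± 0.21) and that of TCDF 3.55-fold (1.83 ± 0.21). On another probe of Cyp1b1 the log2 differences were 1.66, 0.57 and 0.39, in the same order. The call of Cyp1b1 was kept in 19 of 19 alternatives for TCDD, in 17 of 19 for PeCDF and in 12 of 19 for TCDF. On its unsaturated probe Cyp1a2 rose with the dose of TCDD (1.44 ± 0.25), TCDF (1.74 ± 0.25) and PeCDF (1.85 ± 0.25). With TCDD, Ereg (2.78 ± 0.25), Areg (2.27 ± 0.32), Aldh3a1 (2.19 ± 0.51) and Tiparp (1.58 ± 0.35) were higher at the upper dose, and Tmem255b (-1.90 ± 0.19), Zfp354a (-1.69 ± 0.13), Acly (-1.65 ± 0.21) and Onecut1 (-1.63 ± 0.23) lower. TCDF raised Ddit4l, an inhibitor of mTOR (0.65 ± 0.07), and Lect2, a hepatokine (0.62 ± 0.06), and lowered Tmem255b (-1.41 ± 0.19), Slc2a5 (-1.06 ± 0.13), Zfp354a (-0.99 ± 0.13) and Anxa13 (-0.88 ± 0.11). PeCDF raised Defb1 (0.98 ± 0.10), Selenbp1 (0.97 ± 0.12) and Lect2 (0.93 ± 0.06), and lowered Slc2a5 (-1.23 ± 0.13), Slc37a4 (-0.79 ± 0.10), Zap70, a T cell kinase (-0.75 ± 0.11), and Gys2, the liver glycogen synthase (-0.70 ± 0.09). In total 486 genes were higher and 817 lower with TCDD, 6 and 25 with TCDF, and 9 and 20 with PeCDF, or 49 in all for PeCDF with the animal as a block. With 1 session alone the counts were 699, 14 and 13, and with the animal within a session as a block 2214, 103 and 117. The balance for TCDD turned to 530 higher and 496 lower with no background correction. Leaving out 1 animal gave 553 (no lower-dose A, 302 higher and 251 lower), 1260 (no lower-dose B, 716 and 544), 2386 (no upper-dose A) and 651 (no upper-dose B) for TCDD, 34 (no lower-dose A, 22 and 12), 19 (no lower-dose B, 11 and 8), 0 (no upper-dose A) and 57 (no upper-dose B) for TCDF, and 2 (no lower-dose A), 125 (no lower-dose B, 106 higher and 19 lower) and 3 (no upper-dose A) for PeCDF.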

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

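The tests of the session and of another Cyp1b1 probe and the count of low-dose genes below were chosen after the result was seen, whereas the test for a single array apart from its group was set before. This test was run 56 times, each on 1 measure over the 4 arrays of a group, and flagged 4 arrays. For independent values chance alone flags about 1 test in 20, whereas these arrays were dye-swap pairs of 2 animals. For Cyp1a2 with TCDD 1 nM, animal B with the test RNA in Alexa555 had a log2 ratio of 2.26, against 1.62 to 1.70 on the other 3 arrays, which were saturated. For Nqo1 with TCDF 10 nM, animal B with the test RNA in Alexa647 had 1.52, against 1.42 on the others. The median signal over background of the test channel was 59.3 for PeCDF 0.02 nM animal B in Alexa647, against 46.6 to 47.1, and 45.8 for PeCDF 2 nM animal A in Alexa647, against 48.9 to 49.3.

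The effect of raising the dose differed between TCDD and TCDF in 20 genes (18 with a higher value for TCDD) and between TCDD and PeCDF in 6 (4 higher), by limma tests of the difference of differences. Of the 18, 15 were genes lower with TCDD 0.01 nM, of which 3 passed the strict filter on dim probes, and of the 4, 3 were such genes, of which 0 passed it. Gpr141 (0.48 ± 0.06) and Kif5a (0.48 ± 0.06) were among the 15, so most of these differences rest on low-dose falls, mainly of probes that fail this filter. Cyp1b1 rose more from the lower to the upper dose with TCDD than with TCDF (2.16 ± 0.30, adjusted p = 0.0464), though another probe of this gene had 1.27 ± 0.19 (adjusted p = 0.0737). Pou3f1 also rose more with TCDD (1.25 ± 0.15, adjusted p = 0.0252), and Pfkfb1 had -0.72 ± 0.09 (adjusted p = 0.0252). Against PeCDF, Pfkfb1 had -0.93 ± 0.09 (adjusted p = 0.015). A shift between sessions common to both doses cancels in these differences.

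The genes that differed between TCDD 1 nM and a furan were weighed against a shift between the sessions. Such a shift would appear at the lower doses too. For the 22 genes that differed from TCDF the median lower-dose difference in the same direction was 0.107 (animal A 0.125, animal B 0.145), against 0.645 at the upper dose. For the 295 that differed from PeCDF it was 0.124 (A 0.0878, B 0.162), against 0.469, so a constant shift as the whole cause was excluded. Whether compound or dose made the difference stays open, since the doses differed in nM and the potency of the compounds was not measured here.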

How the results depend on the processing

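The brightest unsaturated probe, the animal within a session as a block and the fits of 1 session were chosen after the result was seen; all other alternatives were set before. No named value that was called reversed in direction. Many were named for large changes or small p in these same arrays, so a reversal was unlikely from the start. Of 436 named values 269 were called, and their 4853 alternative values kept the call in 4112 cases and lost it in 741. The 2985 alternative values of the others stayed without a call in 2803 cases and gained one in 182. Counts below that are not given stayed within 1.5 times, and the cause was not tested except where stated. Signal over background limits what dim probes can show: with the stricter filter, which tests fewer genes, the counts were 1 (untreated), 67 (TCDD 0.01 nM) and 4 (among the lower doses), and with no filter 28 (untreated), 0 (TCDF 0.1 nM) and 57 (among the lower doses).

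Agilent's log ratio and the series value table gave the same counts: untreated 184, TCDF 0.1 nM 0, TCDF 10 nM 421, PeCDF 2 nM 735, TCDD 1 nM against TCDF 10 nM 2 and against PeCDF 2 nM 7, dose effect of TCDD 732, of TCDF 9 and of PeCDF 7, and among the lower doses 19. No background correction gave TCDF 0.1 nM 2, PeCDF 0.02 nM 2, TCDD against TCDF 5, TCDD against PeCDF 182, PeCDF dose effect 17 and lower doses 61. Every probe on its own gave 0 for TCDF 0.1 nM. With the intensity trend and robust variances TCDF 10 nM gave 507, TCDD against TCDF 11, against PeCDF 127, TCDF dose effect 19 and lower doses 54. A change of at least 1.5-fold, which admits fewer genes, left 4 (untreated), 3 and 508 (TCDD), 94 (TCDF 10 nM), 118 (PeCDF 2 nM), 12 and 76 (TCDD against TCDF and PeCDF), 359 and 17 (dose effects of TCDD and PeCDF) and 1 (lower doses). Untreated RNA as the control gave 61 and 1396 for TCDD, 0 and 184 for TCDF, and 389 for PeCDF 2 nM.

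The animal as a replicate block gave 26 (untreated), 2 (TCDF 0.1 nM), 36 (TCDD against TCDF) and 49 (PeCDF dose effect), and changed no other count by over 1.5 times. The animal within a session as a block gave 56 (untreated), 321 (TCDD 0.01 nM), 6 and 1353 (TCDF), 2647 (PeCDF 2 nM), 260 and 1242 (TCDD against TCDF and PeCDF), and 2214, 103 and 117 (dose effects of TCDD, TCDF and PeCDF). Fits of 1 session, with fewer samples, gave 0 (untreated), 14 (TCDD 0.01 nM) and 699 (TCDD dose effect) in the first, and 0 and 469 (TCDF), 14 (TCDF dose effect) and 13 (PeCDF dose effect) in the second. Array-level fits, which take the arrays of a dye-swap pair as correlated samples, gave with a dye term 280 (untreated), 722 and 6453 (TCDD), 637 and 2822 (TCDF), 612 and 4509 (PeCDF), 2534, 3897 and 22 (TCDD against TCDF, TCDD against PeCDF, PeCDF against TCDF), 3639, 435 and 572 (dose effects) and 344 (lower doses). With the extraction day as a block, in the same order, they gave 268, 672 and 6332, 564 and 2692, 495 and 4400, 2404, 3719 and 16, 3497, 400 and 527, and 301.

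Leaving out 1 animal of a group left a lone sample that was assumed to vary like the other groups. Lowest and highest counts were 474 and 767 (untreated, no A and no B), 245 and 601 (TCDD 0.01 nM, no A and no B), 1595 and 3885 (TCDD 1 nM, no B and no A), 34 and 42 (TCDF 0.1 nM), 64 and 260 (TCDF 10 nM, no A and no B), 0 and 157 (PeCDF 0.02 nM, no A and no B), and 136 and 655 (PeCDF 2 nM, no A and no B). For differences they were 3 and 1770 (TCDD against TCDF, no TCDF A and no TCDD A), 6 and 2293 (TCDD against PeCDF, no TCDD B and no TCDD A), 0 and 23 (PeCDF against TCDF, the latter without TCDF B), 553 and 2386 (TCDD dose effect), 0 and 57 (TCDF dose effect), 2 and 125 (PeCDF dose effect) and 25 and 233 (lower doses).

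Of 299 list tests camera called 122, camera with an estimated correlation 15 and fry 71. Mean correlations over 2 pairs of profiles were taken within an animal, and then across animals, where no DMSO RNA is shared. They were 0.411 and 0.468 (TCDD 1 nM with TCDF 10 nM), 0.426 and 0.298 (TCDD 1 nM with PeCDF 2 nM), and 0.231 and 0.161 (TCDD 0.01 nM with PeCDF 0.02 nM). These moved by less than the standard deviation of the pairs within an animal (0.327, 0.188 and 0.0840). The others moved by more than theirs (0.0545, 0.0171 and 0.334): 0.625 and 0.555 (TCDF 10 nM with PeCDF 2 nM, though with 0.150 across animals), 0.107 and -0.00448 (TCDD 0.01 nM with TCDF 0.1 nM), and 0.516 and 0.0360 (TCDF 0.1 nM with PeCDF 0.02 nM).

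The balance of higher and lower calls turned in some settings, a part of which follows. Untreated cells went from 8 higher and 7 lower to 24 and 450 without animal A and to 142 and 625 without B, and TCDD 0.01 nM from 33 and 124 to 450 and 272 with the dye term and 414 and 258 with the day as a block. TCDF 10 nM went from 384 and 438 to 1567 and 1255 with the dye term, and TCDD 1 nM from 1614 and 2063 to 1549 and 1428 with no background correction. TCDD against TCDF went from 14 and 8 to 588 and 1946 with the dye term, 543 and 1861 with the day as a block, 218 and 1552 without TCDD animal A and 88 and 172 with the animal within a session as a block. TCDD against PeCDF went from 156 and 139 to 1616 and 2281 with the dye term and 564 and 1729 without TCDD animal A. The TCDD dose effect went from 486 and 817 to 302 and 251 without lower-dose animal A and 716 and 544 without B, and the TCDF dose effect from 6 and 25 to 22 and 12 without lower-dose animal A. The PeCDF dose effect went from 9 and 20 to 106 and 19 without lower-dose animal B and 7 and 0 with Agilent's log ratio.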

Other observations

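The tests of dim probes among genes lower with TCDD 0.01 nM and of the shared DMSO RNA were chosen after the result was seen, and so was the spread set beside the latter. Per2, a clock repressor, rose 1.22-fold with PeCDF 2 nM (0.28 ± 0.06) and 1.16-fold with TCDD 1 nM (0.22 ± 0.06).

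Camera called 5 of 23 lists in untreated cells against DMSO, where 15 genes were called, and none kept its call with an estimated correlation. The lists of CAR and PXR targets (median 0.09; adjusted p = 0.293 with an estimated correlation), of conjugating enzymes (0.09; adjusted p = 0.637 with an estimated correlation) and of Kupffer cell markers (-0.08; adjusted p = 0.399 with an estimated correlation) were among them.

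Of the 124 genes lower with TCDD 0.01 nM, 121 were not lower with 1 nM, and their median log2 ratio was -0.355 at the lower and 0.00788 at the upper dose. Probes near background predict that few of them pass a strict filter, and 43.0% did, against 59.5% to 76.0% of random sets. The filter also requires signal in the TCDD 0.01 nM test channels, in which these genes were chosen for being lower. The smaller share therefore cannot tell dim probes from the fall itself. A shift shared by the session predicts a like fall in untreated cells, where the median was 0.00466 (A -0.0103, B 0.0163), so that cause was excluded. A response to the low dose alone stays open, as 52 of the 121 passed the strict filter.

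Differences between animals A and B were shared mainly by TCDF 0.1 nM, TCDF 10 nM and PeCDF 0.02 nM, whose pairs correlated by 0.501 to 0.564. PeCDF 2 nM correlated with these groups by 0.0686, 0.134 and 0.299, and with those of the first session by -0.0956 to 0.290. Over all 6 pairs of groups in the second session the median correlation was 0.400, against 0.0161 over 3 pairs in the first. A shared DMSO RNA would cancel in the dose differences, and the deviations of those of TCDF and PeCDF correlated by 0.231. Pairs of groups across sessions correlated by -0.393 to 0.290, and the TCDD dose difference by 0.268 and 0.380 with those of TCDF and PeCDF. The 0.231 therefore does not decide whether a shared RNA was the cause. Over the 23624 genes that pass the strict filter the median correlation was 0.440, which excludes dim probes. A DMSO RNA used on all arrays of an animal would be shared in the first session and across sessions too. The median correlations there were 0.0161 and -0.0619, which argues against such an RNA as the main cause of the 0.400. A DMSO RNA shared within the second session only, an animal-specific response to both furans and a technical effect of the second session stay open.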
